A study of Mus musculus with 12 samples.

How the data were processed

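The series measures RNA of mouse CD4 T cells differentiated in culture, with and without a transient block of calcium entry. Per the labels, naive CD4 T cells of wild-type female mice aged 8 to 12 weeks were enriched magnetically from spleen and lymph nodes. They were activated for 48 h with plate-bound antibodies to CD3 and CD28. Th1 cultures received anti-IL-4 and IL-12, and pathogenic Th17 cultures, called pTh17 here, received anti-IL-4, anti-IFN-γ, IL-6, IL-23 and IL-1β. From 48 h the medium held recombinant human IL-2 at 10 U/ml, which the labels give for Th1 cells only. BTP2 blocks CRAC channels, the plasma membrane channels of store-operated calcium entry, and was present from 24 h to 48 h in the treated cultures. On day 4 the cells were restimulated for 5 h with the same antibodies before RNA was taken. The labels state that cells of 3 biological replicates were pooled after harvest and then divided. The 3 libraries of a condition are therefore taken as technical replicates of 1 pool. Every p value here measures the spread between such libraries only and does not extend to other animals.

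Libraries were stranded, depleted of ribosomal RNA and read single-end on an Illumina instrument. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.19.1.403, aligned with STAR 2.7.9a and summed per gene in Partek, whose version is not given in the sources used here. The notes name both GRCm39 and mm10 without a role for either, so no coordinates are printed. The annotation release and the strand setting of the counting step are not given in the sources used here, so reads of overlapping genes on opposite strands are not separated with certainty. Near-identical copies are likewise uncertain, among them Hspa1a and Hspa1b, Rps3a3 and its parent gene, Ly6c2, Gzmd and Gzme, Igtp and its neighbour, the histone and ribosomal protein genes, and the Y-linked genes with X-linked partners. The deposited values are whole-number counts per gene and, in a second table, CPM (counts scaled to a common library total) to which the authors added 0.0001. That second table equals the counts divided by the library total and scaled to CPM, plus that offset, with a largest relative difference of 4.9e-06.

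Everything below was computed from the counts with R 4.3.3. The tables list 55357 genes, of which 28333 were detected and 3276, with 2.97% of the reads, carry no symbol. Totals ran from 15148632 to 20351350 counts over the 12 libraries, and a floor of 3 counts equals 0.147 to 0.198 CPM. The edgeR 4.0.16 filter with a minimum count of 10 kept 13788 genes. Trimmed mean (TMM) factors ran from 0.974 to 1.04. One quasi-likelihood model in edgeR with a term for each of the 4 groups was fitted to the 12 libraries, and its common biological coefficient of variation was 8.46%. Levels are mean CPM ± SD over n = 3 libraries per group, and folds and log2 fold changes are model estimates, with their standard error (SE). Technical replicates still spread more than counting alone, where a chi-square per gene of 1 is the reference, with 3.1 to 23.8 here. Libraries sharing a replicate number were not treated as pairs: only 4 of 12 libraries correlated best with their own number.

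The comparisons were BTP2 over control in Th1, BTP2 over control in pTh17, the difference between those effects (pTh17 minus Th1), and pTh17 over Th1 in controls. They were fixed before the data were examined, as were the lists, the rule for naming genes and the alternatives, apart from those called added. Each used edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment over all tested genes, a threshold of 0.05 on the adjusted p and a separate mark at 2-fold. Genes named are the 6 largest rises and 6 largest falls with an adjusted p under the threshold, at least 5 CPM and full separation of the libraries (for the difference, no separation rule). Unnamed loci and receptor or antibody segments were passed over. To these were added genes fixed for each comparison and up to 3 members of each list with the largest called changes, or up to 2 of the most abundant where none was called. A few genes these rules select are not reported here.

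The 42 lists, assembled from general knowledge, are Th1 program, Th17 program, pathogenic Th17, non-pathogenic Th17, Th2, Treg, Tfh, NFAT and calcium-dependent activation, store-operated calcium entry, calcineurin and NFAT components, inhibitory receptors, naive and memory genes, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, amino acid transport, integrated stress response, unfolded protein response, hypoxia, MYC targets, S phase, G2/M, apoptosis, p53 targets, interferon-stimulated genes, NF-kB targets, AP-1 genes, STAT5 feedback, cytotoxic genes, chemokines, T cell receptor signalling, histones, ribosomal proteins, and markers of CD8 T cells, B cells, myeloid cells, dendritic cells, NK cells and erythroid cells or platelets. The last list had 0 tested members, which leaves 41. Lists were tested with camera in limma 3.58.1 at the preset correlation of 0.01, adjusted over lists within a comparison, and again with the correlation estimated per list. For the lists described, the numbers of members that rose, fell or did not pass are given, both adjusted over all genes and adjusted over the list alone. For some uncalled lists of the difference and of the controls these numbers are left out.

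Alternatives were relative log expression factors, library size alone, no filter, a filter at 5 CPM, DESeq2 1.42.0, limma-voom, a replicate block, a test against 1.5-fold, leaving out each library, limma-trend on log2(CPM + 1) with and without the filter and on log2(CPM + 0.0001), and a fit to the 6 libraries of a comparison alone. Lists were also tested with fry and without members shared between lists. Leaving out X- and Y-linked genes, and library size alone for lists, were added after the data were seen. An alternative counts as the same when its call and, if called, its sign are unchanged. When neither value passes the threshold the sign is not counted.

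The pipeline was tested on simulated data with planted changes. For 2-fold changes it recovered 82.9% in Th1, 86.6% in pTh17, 60.7% for the difference and 77.4% in the controls, with 19, 10, 7 and 2 false calls among 13788 genes. A planted list was called, with 0 others called. Few genes were changed: in Th1 66 by 1.5-fold, 76 by 2-fold and 58 by 4-fold, besides the planted list. In the data 49.65% to 55.7% of the genes were called, so the check does not cover scaling or false calls at that share. Genes were simulated independently of each other, so this check cannot show false list calls that arise from correlation within lists. For genes with 0 to 3 counts in a group, ratios come from summed counts with 95% exact binomial intervals, or as a lower limit against the floor of 3 counts. These intervals cover counting error only and leave out the further spread between libraries. Reads were not realigned, and transcript isoforms and splicing were not analysed here.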

Results

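The data are 12 libraries of CD4 T cells in 4 groups of 3: Th1 control, Th1 BTP2, pTh17 control and pTh17 BTP2. Each holds 15148632 to 20351350 counts, and 13788 genes were tested. By the labels the 3 libraries of a group come from 1 pool of cells, so the tests describe spread between libraries of that pool. In the list results below, counts adjusted over the list alone equal those adjusted over all genes except where both are given.

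The first comparison asks what BTP2, present on the second day of culture, changed in Th1 cells by day 4. Expression of Il10, an anti-inflammatory cytokine made by strongly stimulated Th1 cells, fell from 940.5 ± 154 to 165.6 ± 38.1 CPM (5.50-fold, n = 3, adjusted p = 1.76e-08). Il2, the T cell growth factor whose promoter is a classical target of the calcium-dependent factor NFAT, rose from 265 ± 38.1 to 732.8 ± 121 CPM (2.86-fold, adjusted p = 6.95e-06). Ifng, the defining Th1 cytokine, measured 8719 ± 458 CPM in controls and 7435 ± 484 CPM after BTP2 (log2 fold change -0.18, SE 0.0954, adjusted p = 0.126). Tbx21, which encodes the lineage factor T-bet, measured 229.4 ± 15 and 202.2 ± 9.56 CPM (log2 fold change -0.13, adjusted p = 0.26). Ctla4, an inhibitory receptor induced by activation, fell from 668.7 ± 4.55 to 75.59 ± 31.1 CPM (8.57-fold, adjusted p = 2.83e-08).

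Other genes chosen in advance moved in both directions. Tnf rose from 673.6 ± 42.1 to 886.9 ± 94.1 CPM (1.36-fold, adjusted p = 0.00289), and the chemokine receptor gene Cxcr3 rose 2.66-fold from 18.35 ± 2.43 CPM (adjusted p = 9.76e-06). Il12rb2, a subunit of the IL-12 receptor, fell 2.07-fold from 693.1 ± 76.8 CPM (adjusted p = 1.01e-05). Csf2, encoding GM-CSF, rose 1.36-fold to 444.5 ± 145 CPM (adjusted p = 0.0331). That call was lost without Th1 BTP2 library 2 (adjusted p = 0.259) or Th1 control library 1 (0.127) or 3 (0.0938), and in DESeq2 (0.0771). The largest rise under the naming rule was in Wnt3, a secreted ligand, from 0.432 ± 0.0346 to 17.2 ± 3.26 CPM (40.7-fold). It was followed by the Fc receptor-like gene Fcrl1 (13.1-fold, to 26.2 ± 10.3 CPM), the zinc transporter gene Slc30a3 (12.7-fold, to 8.30 ± 2.64 CPM) and the carbonic anhydrase gene Car2 (10.4-fold, to 92.1 ± 27.5 CPM). The potassium channel gene Kcnh4 rose 10.4-fold to 15.5 ± 4.8 CPM and Lrp4 8.85-fold to 5.37 ± 0.958 CPM. The largest fall under that rule was in Myof, which encodes a membrane repair protein of the ferlin family, from 6.07 ± 1.04 CPM (32.1-fold). Its relative Dysf fell 17.9-fold from 8.28 ± 1.1 CPM. Falls were also seen in Mcf2l (27.2-fold, from 12.5 ± 2.35 CPM), Shroom3 (19.6-fold, from 11.9 ± 1.59 CPM), Tgm1 (17.8-fold, from 5.94 ± 1.37 CPM) and Stom (12.6-fold, from 13.8 ± 0.406 CPM). Without Th1 BTP2 library 2 the log2 fold changes of Dysf and Mcf2l became -5.19 and -5.48, from -4.17 and -4.77.

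The S phase and G2/M lists were lower after BTP2 in Th1. Of the 18 S phase genes, 0 rose, 17 fell and 1 did not pass (median log2 fold change -0.73, camera adjusted p = 6.51e-11, and adjusted p = 0.296 with an estimated correlation). Cdc6, a replication licensing factor, fell from 77.92 ± 5.95 to 20.19 ± 0.299 CPM (3.73-fold). Rrm2, the nucleotide reductase subunit, fell 3.11-fold from 134.9 ± 27.2 CPM. For G2/M genes, 0 rose and 16 fell of 20 (17 adjusted over the list alone, median -0.68, camera adjusted p = 0.000128, adjusted p = 0.672 with an estimated correlation). The spindle checkpoint kinase gene Bub1 was 2.51-fold lower. MYC targets moved the opposite way: 20 rose, 0 fell and 1 did not pass (median 0.46, adjusted p = 4.21e-08, adjusted p = 0.243 with an estimated correlation). Ncl, encoding nucleolin of the nucleolus, rose from 2812 ± 47.1 to 4361 ± 364 CPM, and Cad, of pyrimidine synthesis, rose 1.62-fold. Histones gave 0 up and 4 down of 12 (adjusted p = 0.253). Hist1h4i was 3.21-fold lower, and ribosomal protein genes 4 up and 1 down of 30 (adjusted p = 0.39).

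Lists of glycolysis, hypoxia, fatty acid synthesis, the integrated stress response and p53 targets were lower, and 7 other lists of metabolism and stress were not called. Among glycolysis genes 2 rose, 14 fell and 2 did not pass (median -0.74, adjusted p = 2.62e-07, adjusted p = 0.296 with an estimated correlation). Tpi1 fell from 415.4 ± 54.8 to 120.8 ± 22.4 CPM and the lactate exporter gene Slc16a3 fell 4.03-fold. Hypoxia genes gave 0 up, 14 down and 3 not passing (median -1.04, adjusted p = 3.74e-08, adjusted p = 0.243 with an estimated correlation), and the mitophagy receptor gene Bnip3 fell 7.66-fold from 27.33 ± 3.79 CPM (log2 fold change -2.94, and -3.71 without Th1 BTP2 library 2). Fatty acid synthesis genes gave 2 up, 8 down and 2 not passing (median -0.66, adjusted p = 0.00988, adjusted p = 0.296 with an estimated correlation). The desaturase gene Scd2 was 2.71-fold lower from 545.4 ± 34.3 CPM. The integrated stress response gave 2 up, 10 down (11 adjusted over the list alone) and 6 not passing (median -0.39, adjusted p = 0.000289, adjusted p = 0.504 with an estimated correlation). Ddit4 fell 2.56-fold from 61.12 ± 1.83 CPM. Of the p53 targets 1 rose, 10 fell and 3 did not pass (median -0.75, adjusted p = 0.000128, adjusted p = 0.296 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a was 2.94-fold lower from 452.4 ± 60.9 CPM. Uncalled lists here were oxidative phosphorylation (8 up, 6 down of 34, adjusted p = 0.752), mitochondrially encoded genes (0 and 0 of 7, 0.993) and fatty acid oxidation (2 and 5 of 14, 0.21). So were cholesterol synthesis (9 and 13 of 24, 0.683), amino acid transport (3 and 2 of 10, 0.614), apoptosis (5 and 10 of 20, 0.619) and the unfolded protein response (0 and 6 of 17, 0.362).

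Interferon-stimulated genes, which amplify antiviral defence, gave 2 up, 19 down and 3 not passing in Th1 (median -1.37, adjusted p = 2.59e-05, adjusted p = 0.426 with an estimated correlation). The nucleic acid sensor gene Zbp1 fell from 42.56 ± 2.53 to 12.4 ± 5.2 CPM (3.32-fold) and Oas3 fell 2.95-fold. STAT5 feedback genes gave 1 up, 9 down and 2 not passing (median -0.81, adjusted p = 0.00495, adjusted p = 0.631 with an estimated correlation). The cytokine gene Lif was 3.33-fold lower from 352.5 ± 23.1 CPM. NF-kB targets gave 13 up, 4 down and 2 not passing (median 0.32, adjusted p = 0.0114, adjusted p = 0.507 with an estimated correlation), a call lost without Th1 BTP2 library 2 (adjusted p = 0.0834) and with the filter at 5 CPM (0.0506). Tnfaip3, a feedback inhibitor of NF-kB, rose from 353.1 ± 1.84 to 602.2 ± 55.6 CPM. Of the pathogenic Th17 genes 1 rose, 10 fell and 8 did not pass (median -0.46, adjusted p = 0.00495, adjusted p = 0.171 with an estimated correlation, and 0.0915 without shared members). Il7r was 2.83-fold lower from 245.3 ± 6.23 CPM. Treg genes gave 2 up, 8 down (9 adjusted over the list alone) and 4 not passing (median -0.57, adjusted p = 0.00495, adjusted p = 0.321 with an estimated correlation). Entpd1 was 6.77-fold lower. Without members shared with other lists the test changed sign (adjusted p = 0.747). Tfh genes gave 6 up, 3 down and 1 not passing (median 0.43, adjusted p = 0.00225, adjusted p = 0.171 with an estimated correlation). Bcl6, the Tfh lineage repressor, rose from 21.69 ± 1.55 to 77.79 ± 8.78 CPM and Slamf6 rose 5.46-fold.

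Lists of calcium signalling and identity were mixed. NFAT and calcium-dependent activation genes gave 10 up, 6 down (7 adjusted over the list alone) and 8 not passing (median 0.20, adjusted p = 0.157). That list passed without Th1 BTP2 library 3 (0.015) and without members shared with other lists (0.00882). Among its members Xcl1, a chemokine for cross-presenting dendritic cells, rose 7.67-fold from 419.5 ± 27.7 CPM, and Il21, the helper cytokine, fell from 288.4 ± 31.2 to 71.3 ± 40.3 CPM. Genes of store-operated calcium entry gave 9 up, 9 down and 4 not passing (adjusted p = 0.902). Stim2, an endoplasmic calcium sensor, rose from 67.34 ± 3.8 to 161.6 ± 21.6 CPM, and Atp2b4, a calcium pump of the plasma membrane, fell 3.51-fold. Calcineurin and NFAT components gave 4 up, 6 down and 6 not passing (adjusted p = 0.619). The Th1 program gave 7 up, 7 down and 6 not passing (adjusted p = 0.683), with Ly6c2 up 8.71-fold and Hlx down 4.71-fold. The Th17 program gave 6 up, 9 down (11 adjusted over the list alone) and 5 not passing (adjusted p = 0.556). Non-pathogenic Th17 genes gave 4 up, 4 down and 1 not passing (adjusted p = 0.902), and Th2 genes 3 up, 3 down and 4 not passing (0.642).

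Surface receptor and effector lists were not called in Th1. Inhibitory receptors gave 7 up and 6 down of 16 (adjusted p = 0.705), although Prdm1, the repressor Blimp-1, fell 6.54-fold from 119.1 ± 3.03 CPM. Naive and memory genes gave 6 up and 8 down of 16 (adjusted p = 0.902), with Bach2, which restrains effector differentiation, up 2.60-fold from 153.1 ± 15.3 CPM. Chemokines gave 9 up and 8 down of 20 (0.683) and cytotoxic genes 6 up and 2 down of 16 (0.356). AP-1 genes gave 8 up and 6 down of 20 (7 down adjusted over the list alone, adjusted p = 0.619), and Dusp4, a MAP kinase phosphatase gene, rose 2.24-fold. T cell receptor signalling genes gave 5 up and 7 down of 20 (0.683), and Cd4 fell from 505.8 ± 31.5 to 311.8 ± 64.1 CPM. The median, the mean and the test did not share a sign for the Th1 program, non-pathogenic Th17, store-operated calcium entry, inhibitory receptors, naive and memory genes, oxidative phosphorylation, AP-1, cytotoxic genes, chemokines and NK cell markers.

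Of the marker lists of other cell types, only that of CD8 T cells was called with BTP2 in Th1, though single markers of others moved too. These changes accompany every group above. CD8 T cell markers gave 3 up, 0 down and 1 not passing (median 1.39, adjusted p = 0.00566, adjusted p = 0.362 with an estimated correlation). Cd8a rose from 33.33 ± 12.4 to 168.2 ± 66.4 CPM. The summed level of the CD8 markers was 243.2 ± 28.6 CPM in controls and 683.8 ± 187 CPM after BTP2. In Th1 BTP2 libraries 1, 2 and 3 it was 708.9, 485.9 and 856.7 CPM. Whether RNA of CD8 T cells makes up part of the Th1 changes was not tested. B cell markers gave 5 up and 0 down of 10 (6 and 1 adjusted over the list alone, adjusted p = 0.0541, but 0.0239 with the replicate block, 0.0306 with library size alone and 0.0263 without Th1 BTP2 library 2), with summed levels of 34.62 ± 3.42 and 33.95 ± 4.55 CPM. The IgE receptor gene Fcer2a had 134 counts against 3, a ratio of 45.6 (95% interval 15.3 to 224, counting error only), and its log2 fold change went from 5.38 to 6.25 without Th1 control library 3. Dendritic cell markers gave 5 up and 1 down of 8 (6 up adjusted over the list alone, adjusted p = 0.224). Their summed level went the other way, from 203.3 ± 14.2 to 112.2 ± 7.64 CPM. H2-Ab1, of class II antigen presentation, fell from 166.4 ± 12.6 to 35.51 ± 16.9 CPM. Myeloid markers gave 1 up and 3 down of 6 (4 adjusted over the list alone, 0.619), with sums of 13.08 ± 1.49 and 7.787 ± 1.84 CPM. NK cell markers gave 1 up and 1 down of 6 (1 and 0 adjusted over the list alone, 0.747), with sums of 17 ± 0.51 and 24.46 ± 1 CPM. Erythroid and platelet markers were near absent, with summed levels of 0.104 ± 0.136 and 0.0577 ± 0.1 CPM. Y-linked genes were near absent in both Th1 groups.

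Across the 13788 genes, 6846 passed in Th1 (3234 higher, 3612 lower after BTP2), 1818 of them by at least 2-fold (424 higher, 1394 lower). Library size alone gave 2762 higher and 3975 lower. Of 41 lists, 4 were called up and 11 down, and 0 with an estimated correlation, where 7653 genes passed without adjustment, fry called 28 lists and DESeq2 called 6597 genes. Ifng passed with library size alone (adjusted p = 0.0469), with no filter (0.0301) and in limma-trend on log2(CPM + 0.0001) (0.0444).

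The second comparison asks what the same treatment changed in pTh17 cells. Il17a and Il17f, the defining Th17 cytokines, fell from 228.5 ± 20.5 to 23.02 ± 3.98 CPM (10.3-fold, n = 3, adjusted p = 5.24e-10) and from 373.9 ± 38 to 22.06 ± 1.52 CPM (17.5-fold, adjusted p = 6.59e-11). Il2 fell from 4528 ± 262 to 598 ± 201 CPM (7.84-fold, adjusted p = 7.31e-09), opposite in direction to Th1. Tbx21 rose from 61.82 ± 6.88 to 184.2 ± 23 CPM (2.89-fold, adjusted p = 8.61e-09), close to the level in Th1 libraries. Ccl20, the chemokine ligand of CCR6 on Th17 cells, fell from 104 ± 10.5 to 1.37 ± 0.47 CPM (76.8-fold, adjusted p = 3.49e-13).

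Il23r, the receptor for the cytokine that sustains pathogenic Th17 cells, fell from 5.34 ± 0.0633 to 0.984 ± 0.227 CPM (5.53-fold, adjusted p = 3.47e-07). Il22, a cytokine acting on epithelium, fell 2.33-fold from 1.81 ± 0.407 CPM (0.00404) and Il10 fell 1.86-fold from 49.08 ± 6.89 CPM (0.000279). Foxp3, the Treg lineage factor, rose from 5.12 ± 0.527 to 12.33 ± 3.38 CPM (2.32-fold, adjusted p = 0.000188). Csf2 measured 304.1 ± 11.7 and 365.5 ± 29.9 CPM (log2 fold change 0.22, adjusted p = 0.27), and passed with no filter (0.0113) and in a fit to the 6 libraries alone (0.0296). The largest rise under the naming rule was in Il9, a mast cell growth factor, with 368 counts against 3, a ratio of 128 (95% interval 43.4 to 623, counting error only). Its log2 fold change went from 6.78 to 7.62 without pTh17 control library 2. Hspa1a, encoding a heat shock protein, rose 35.2-fold from 2.87 ± 0.409 to 104.5 ± 4.9 CPM and its near-identical copy Hspa1b 28.2-fold to 113.7 ± 2.07 CPM. Hspb1 rose 54.8-fold to 6.61 ± 0.286 CPM. Fcer2a rose 52.8-fold to 16.3 ± 13.6 CPM and the matricellular gene Ccn3 27.9-fold to 15.5 ± 2.95 CPM. The log2 fold change of Fcer2a went from 5.72 to 4.76 without pTh17 BTP2 library 1, and that of Hspb1 from 5.78 to 7.55 without pTh17 control library 3. Among the largest falls were the ribosomal gene copy Rps3a3 (61.4-fold, from 41.35 ± 5.63 CPM) and 4 Y-linked genes. Rps3a3, on chromosome 13, was far higher in pTh17 controls than in each other group, as were the Y-linked genes. Its fall thus cannot be told apart from a difference between the pools.

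**Figure D1:**
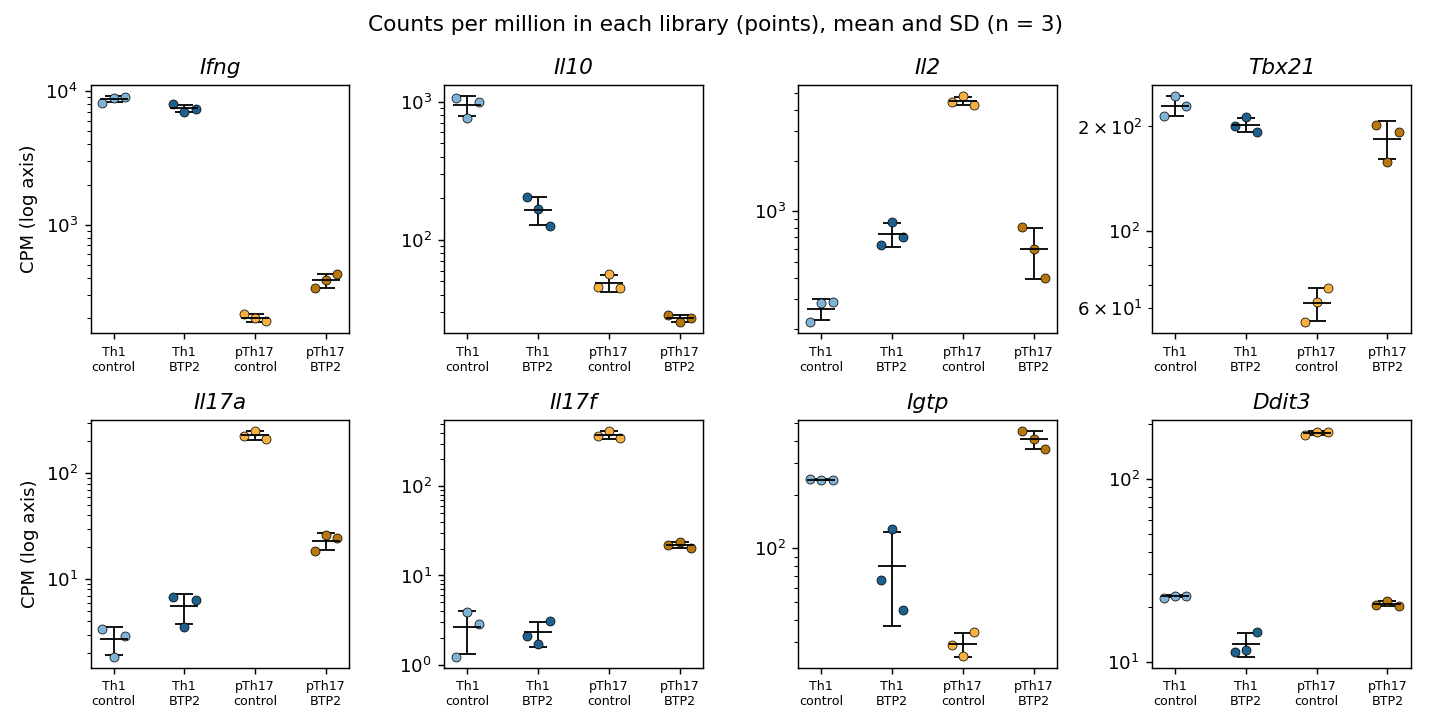
Levels of Ifng, Il10, Il2, Tbx21, Il17a, Il17f, Igtp and Ddit3 in CPM on a log axis for Th1 control, Th1 BTP2, pTh17 control and pTh17 BTP2, with points for libraries and bars for mean and SD (n = 3). Il2 ran from 265 to 732.8 CPM in Th1 and from 4528 to 598 CPM in pTh17.

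The pTh17 controls differed from the other groups in sex-linked transcripts, although the labels give all mice as female. The summed Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 4606, 4225 and 4104 counts in the pTh17 control libraries and 1 to 10 counts in each of the other 9. Control over BTP2 ratios in pTh17 were 2030 for Eif2s3y (4231 counts against 2, 95% interval 561 to 16700), 1940 for Kdm5d (2020 against 1, 347 to 76500) and 788 for Uty (822 against 1, 141 to 31200). Ddx3y fell 512-fold from 107.6 ± 9.12 CPM (a log2 fold change of -9.75 without pTh17 BTP2 library 1). Without that library the log2 fold changes of Kdm5d and Uty went from -10.52 to -12.42 and from -9.23 to -11.12. Xist, expressed from the inactive X chromosome of female cells, measured 30.11 ± 14.5 CPM in pTh17 controls and 602.9 ± 79.3 CPM in pTh17 BTP2. It measured 716 ± 26.1 CPM in Th1 controls and 849.9 ± 69.7 CPM in Th1 BTP2. In pTh17 control libraries 1, 2 and 3 it was 37.1, 13.47 and 39.76 CPM, which is uneven for portions of 1 pool. Each comparison that uses the pTh17 controls thus also compares libraries that differ in sex-linked RNA, and this holds for every gene group in them.

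**Figure D2:**
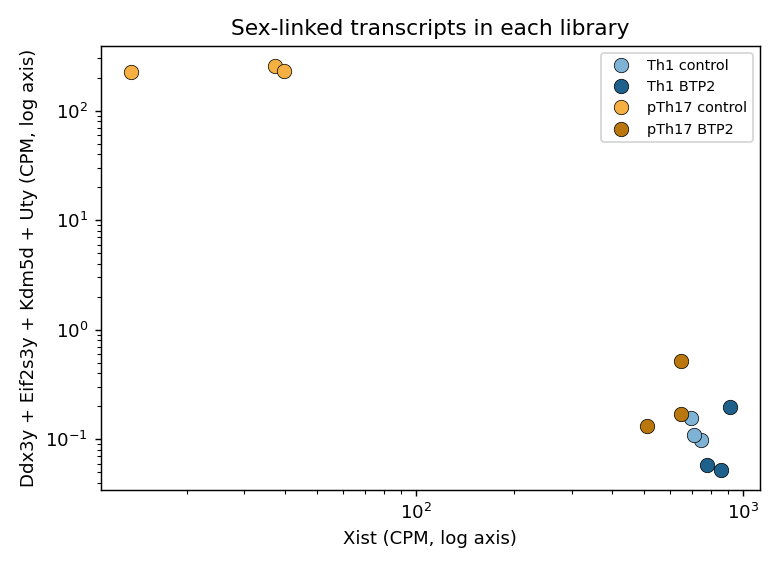
Summed level of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty against the level of Xist, both in CPM on log axes, for the 12 libraries (points coloured by group). The pTh17 controls lie at 227.7 to 255.5 CPM of Y-linked RNA and the other libraries at 0.0523 to 0.515 CPM.

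The Th17 program fell and Th2 genes rose in pTh17. The Th17 program gave 3 up (4 adjusted over the list alone), 16 down and 1 not passing (median -1.22, camera adjusted p = 8.88e-07, and 0.0296 with an estimated correlation), with Il24, an IL-10 family cytokine, moving against it from 10.64 ± 4.31 to 225.6 ± 10.1 CPM. Th2 genes gave 8 up, 2 down and 0 not passing (median 1.18, adjusted p = 1.93e-08, and 0.04 with an estimated correlation). Il4, the defining Th2 cytokine, rose from 8.35 ± 0.694 to 71.89 ± 18 CPM (8.33-fold), Il13 rose 5.07-fold to 507.9 ± 15.5 CPM and Ccr8 rose 7.16-fold. Non-pathogenic Th17 genes gave 5 up, 3 down (4 adjusted over the list alone) and 1 not passing (median 0.78, adjusted p = 0.0139, adjusted p = 0.145 with an estimated correlation). The aryl hydrocarbon receptor gene Ahr was 3.47-fold higher. Pathogenic Th17 genes gave 4 up, 7 down and 8 not passing (adjusted p = 0.518). Ccl5 was 4.13-fold lower. Treg genes gave 7 up, 4 down and 3 not passing (median 0.28, adjusted p = 0.0634, but 0.0206 without pTh17 BTP2 library 1 and 0.0101 without shared members). Ikzf2, encoding Helios, rose from 27.76 ± 2.94 to 108.6 ± 12.1 CPM. The Th1 program gave 5 up, 7 down and 8 not passing (0.948) and Tfh genes 3 up, 4 down and 3 not passing (0.948). Sex-linked RNA separated the compared groups here, as given above.

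The integrated stress response, the unfolded protein response and amino acid transport fell as lists in pTh17. For the integrated stress response, the program started by phosphorylation of eIF2α, 0 rose, 17 fell and 1 did not pass (median -1.34, adjusted p = 4.3e-24, and 0.0417 with an estimated correlation). Ddit3, encoding CHOP, fell from 179.1 ± 4.26 to 20.71 ± 0.66 CPM (8.93-fold), Trib3 fell 9.07-fold from 202.5 ± 5.35 CPM and Chac1 fell 16.8-fold. The unfolded protein response gave 0 up, 13 down (14 adjusted over the list alone) and 4 not passing (median -0.47, adjusted p = 6.13e-06, adjusted p = 0.211 with an estimated correlation). Herpud1 fell from 653.8 ± 26.1 to 88.84 ± 8.84 CPM. Amino acid transport gave 1 up, 9 down and 0 not passing (median -0.71, adjusted p = 6.13e-06, adjusted p = 0.145 with an estimated correlation). Slc7a5, the leucine transporter, fell from 1468 ± 69.3 to 564.8 ± 52.8 CPM. Apoptosis genes gave 5 up, 9 down and 6 not passing (adjusted p = 0.0825, Bbc3 2.90-fold lower) and p53 targets 7 up, 5 down and 2 not passing (0.974, Trp53inp1 4.29-fold lower).

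Lists of S phase, ribosomal proteins, cholesterol synthesis, oxidative phosphorylation and glycolysis were higher in pTh17. S phase genes gave 13 up, 0 down and 5 not passing (median 0.39, adjusted p = 0.00113, adjusted p = 0.545 with an estimated correlation). The helicase gene Mcm2 rose from 147.5 ± 4.73 to 286.8 ± 32 CPM. Ribosomal protein genes gave 26 up (28 adjusted over the list alone), 0 down and 4 not passing (median 0.35, adjusted p = 2.34e-05, adjusted p = 0.463 with an estimated correlation). Rps2 was 1.45-fold higher from 370.4 ± 31.9 CPM. Cholesterol synthesis gave 14 up (15 adjusted over the list alone), 1 down and 9 not passing (median 0.33, adjusted p = 0.000229, adjusted p = 0.145 with an estimated correlation). Oxidative phosphorylation gave 21 up, 0 down and 13 not passing (median 0.23, adjusted p = 0.00816, adjusted p = 0.576 with an estimated correlation). Glycolysis gave 11 up, 5 down and 2 not passing (median 0.55, adjusted p = 0.0347, adjusted p = 0.576 with an estimated correlation), a call lost without pTh17 BTP2 library 1 (0.109) or pTh17 control library 1 (0.0612) and with the filter at 5 CPM (0.0679). Aldoa rose from 1237 ± 133 to 2777 ± 182 CPM. MYC targets gave 11 up and 1 down of 21 (adjusted p = 0.0967), called without pTh17 BTP2 library 2 (0.0486). Hypoxia genes gave 10 up and 4 down of 17 (10 and 5 adjusted over the list alone, 0.579), and Vegfa, the angiogenic factor, fell 3.76-fold from 176 ± 1.18 CPM. Also uncalled were G2/M (7 up, 2 down of 20, 0.328), histones (7 and 1 of 12, 8 and 1 adjusted over the list alone, 0.0945, but 0.0437 without pTh17 BTP2 library 3), fatty acid synthesis (5 and 3 of 12, 0.523), fatty acid oxidation (6 and 1 of 14, 6 and 2 adjusted over the list alone, 0.202) and mitochondrially encoded genes (0 and 0 of 7, 0.974, mt-Co1 at 4058 ± 344 and 3588 ± 893 CPM).

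Lists of cytokine signalling and effector genes moved both ways. STAT5 feedback genes gave 6 up, 1 down and 5 not passing (median 0.47, adjusted p = 5.66e-05, adjusted p = 0.434 with an estimated correlation). Socs1, a feedback inhibitor of JAK kinases, rose from 30.51 ± 4.09 to 295 ± 17.4 CPM. Interferon-stimulated genes gave 12 up, 5 down and 7 not passing (median 0.66, adjusted p = 0.0342, adjusted p = 0.585 with an estimated correlation). Igtp, an immunity-related GTPase, rose from 29.29 ± 4.41 to 406.3 ± 46.9 CPM and Irf1 rose 9.45-fold. That list call was lost with the filter at 5 CPM (0.27), with library size alone (0.0519) and without pTh17 control library 1 (0.0596) or pTh17 BTP2 library 1 (0.0638). NF-kB targets gave 3 up, 11 down and 5 not passing (median -0.40, adjusted p = 0.00092, adjusted p = 0.391 with an estimated correlation). Tnf fell from 1401 ± 204 to 449.1 ± 39.9 CPM. Cytotoxic genes gave 3 up, 12 down and 1 not passing (median -1.22, adjusted p = 0.000161, adjusted p = 0.141 with an estimated correlation), and granzyme A gene Gzma fell 8.21-fold from 158.8 ± 11.1 CPM. Store-operated calcium entry genes gave 2 up, 11 down and 9 not passing (median -0.36, adjusted p = 0.0258, adjusted p = 0.517 with an estimated correlation), a call lost without pTh17 BTP2 library 1 (0.0644) and with the filter at 5 CPM (0.0648). The potassium channel gene Kcna3 fell from 153.1 ± 15.2 to 58.44 ± 1.34 CPM.

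NFAT and calcium-dependent activation genes gave 6 up, 10 down and 8 not passing (adjusted p = 0.628). Cd69, the early activation marker, fell from 1765 ± 79.9 to 292.7 ± 61.4 CPM while Il4 rose. Calcineurin and NFAT components gave 3 up, 8 down and 5 not passing (0.51). AP-1 genes gave 5 up, 9 down and 6 not passing (adjusted p = 0.0682, but 0.0349 without pTh17 control library 1 and 0.0166 without pTh17 BTP2 library 3), and Egr1 fell 2.56-fold from 761.6 ± 16.5 CPM. Inhibitory receptors gave 3 up, 6 down and 7 not passing (0.611), with Tox, a factor of T cell exhaustion, up 2.41-fold. Naive and memory genes gave 8 up, 6 down and 2 not passing (adjusted p = 0.881), and Id3, an inhibitor of E proteins, fell 9.84-fold from 367 ± 24.2 CPM. Chemokines gave 9 up, 9 down and 2 not passing (0.202), with Ccr2 down 6.81-fold. T cell receptor signalling genes gave 5 up, 8 down and 7 not passing (0.881), and Prkcq, the kinase PKCθ, rose 4.33-fold from 84.24 ± 3.17 CPM. The median, the mean and the test did not share a sign for pathogenic Th17, Tfh, NFAT, T cell receptor signalling and p53 targets. The medians of the Th1 program, Tfh and mitochondrially encoded genes changed sign under library size alone.

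B cell markers moved with BTP2 in pTh17 alongside every group above: 10 rose and 0 fell of 10 (median 2.50, adjusted p = 0.000318, adjusted p = 0.463 with an estimated correlation). Their sum rose from 41.12 ± 2.26 to 145.5 ± 58.5 CPM, with 213 CPM in library 1 and 109.2 and 114.4 CPM in libraries 2 and 3. Dendritic cell and antigen presentation markers gave 5 up and 2 down of 8 (adjusted p = 0.101, but 0.0207 without pTh17 BTP2 library 2), their sum going from 137.6 ± 7.86 to 332.3 ± 82.3 CPM, with the class II transactivator gene Ciita 10.4-fold higher. CD8 T cell markers gave 0 up and 3 down of 4 (0.0967), myeloid markers 1 and 2 of 6 (0.898) and NK cell markers 0 and 2 of 6 (0.313). Erythroid markers summed to 0.584 ± 0.3 and 0.951 ± 0.549 CPM.

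In pTh17, 7389 genes passed (3613 higher, 3776 lower), 1938 of them by at least 2-fold (981 higher, 957 lower). The majority direction depends on scaling, since library size alone gave 4066 higher and 3396 lower. Of 41 lists, 10 were called up and 7 down, 3 of them also with an estimated correlation. The groups compared differ in sex-linked RNA and in B cell markers, and both rest on 1 pool per condition.

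The third comparison asks which BTP2 effects differed between the lineages. Hspa1a fell from 33.56 ± 12.8 to 2.73 ± 4.11 CPM in Th1 and rose from 2.87 to 104.5 CPM in pTh17, a difference of 8.70 in log2 (SE 0.752, adjusted p = 1.88e-07). Hspa1b (7.78, SE 0.672) and Hspb1 (8.62, SE 0.993) moved the same way. Without Th1 BTP2 library 2 these differences were 11.67, 9.65 and 12.76 for Hspa1a, Hspa1b and Hspb1, and without pTh17 control library 3 that of Hspb1 was 10.39. Il2 differed by -4.49 (SE 0.263, adjusted p = 3.84e-09), having risen in Th1 and fallen in pTh17. Ifng differed by 1.07 (SE 0.136, adjusted p = 9.62e-06), with 201.2 ± 13.3 and 383.6 ± 45.4 CPM in pTh17 control and BTP2 libraries. Il17a (-4.43, SE 0.302) and Il17f (-3.99, SE 0.36) differed, while Csf2 (-0.22, SE 0.228, adjusted p = 0.43) did not pass.

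Tbx21 differed by 1.67 (SE 0.138), Il10 by 1.56 (SE 0.221), Cpne6 by 7.41 (SE 0.454) and the exchange factor gene Mcf2l by 7.31 (SE 0.386). Ccl20 (-8.90, SE 0.321), Wnt3 (-7.05, SE 0.341) and Car2 (-5.65, SE 0.239) differed in the other direction. Without Th1 BTP2 library 2 the values of Cpne6 and Mcf2l were 8.04 and 8.02. Fitted values for the Y-linked genes Kdm5d (-12.40), Eif2s3y (-10.86) and Ddx3y (-9.07) follow the sex-linked difference of the pTh17 controls and are not read as an effect of BTP2. They rest on few counts in the other groups, and Kdm5d lost its call without Th1 BTP2 library 3 (-10.51, adjusted p = 1.0). Leaving out 1 library moved Kdm5d to -14.29 and Ddx3y to -9.82 (pTh17 BTP2 library 1), and Eif2s3y to -11.70 (Th1 control library 2) or -10.06 (Th1 BTP2 library 3). Of genes changed at least 2-fold in both lineages, 343 were lower in Th1 and higher in pTh17 against 99.18 expected for independent effects (Fisher's exact p = 4.29e-109). A further 77 were higher in both against 30.17 expected (exact p = 1.2e-14), 157 lower in both against 96.76 (3.64e-10), and 73 higher in Th1 and lower in pTh17 against 29.43 (3.18e-13). Among all genes passing in both, without the 2-fold mark, same-direction overlaps did not exceed expectation: 805 higher in both against 847.4 (Fisher's exact p = 0.0549) and 954 lower in both against 989.2 (exact p = 0.129). Opposite directions did, with 1194 lower in Th1 and higher in pTh17 against 946.5 (exact p = 7.46e-27) and 1118 the other way against 885.7 (7e-25). Genes are not independent units, so these p values are descriptive. At 2-fold every combination of directions lay above expectation. Independence is therefore a low reference there, and an excess over it does not by itself show linked effects.

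The brackets that follow give a list's median difference, its camera adjusted p and its adjusted p with an estimated correlation. S phase genes had an effect higher in pTh17 than in Th1 for 18 of 18 members (1.08, 4.95e-11, 0.202), G2/M genes for 15 with 0 lower and 5 not passing (0.83, 0.0012, 0.542). Cdc6, for instance, went from 77.92 to 20.19 CPM in Th1 and from 32.09 ± 2.46 to 62.13 ± 7.23 CPM in pTh17. Histones gave 8 higher, 0 lower and 4 not passing (1.38, 0.0286, 0.343), lost with the filter at 5 CPM (0.0646), and p53 targets 6, 3 and 5 (0.38, 0.0172, 0.343). Interferon-stimulated genes gave 17, 3 and 4 (2.29, 7.68e-06, 0.259), and STAT5 feedback genes 9, 1 and 2 (1.504, 1.97e-06, 0.202). Iigp1, an interferon-induced GTPase, went from 25.91 ± 2.67 to 8.08 ± 5.5 CPM in Th1 and from 2.99 ± 1.51 to 46.72 ± 8.85 CPM in pTh17, a log2 difference of 5.56, or 6.27 without Th1 BTP2 library 2. Hypoxia genes gave 12, 3 and 2 (1.59, 7.1e-05, 0.214) and glycolysis genes 13, 2 and 3 (1.44, 1.97e-06, 0.202). Cholesterol synthesis gave 16, 1 and 7 (0.59, 0.00288, 0.202) and fatty acid synthesis 8, 2 (3 adjusted over the list alone) and 2 (0.56, 0.0255, 0.234), with Scd2 lower by 2.71-fold in Th1 and higher by 1.74-fold in pTh17. Ribosomal proteins gave 18, 1 and 11 (0.32, 0.0255, 0.573), a call lost without Th1 control library 3 (0.0526). Treg genes gave 10, 2 and 2 (1.39, 0.000831, 0.202) and Th2 genes 7, 3 and 0 (1.35, 5.53e-05, 0.202), and both lost the call without shared members (0.113 and 0.136).

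In the other direction, with the same order of numbers, NF-kB targets gave 3 higher, 15 lower and 1 not passing (-0.81, 3.75e-05, 0.202), and Tnf rose in Th1 and fell in pTh17. Amino acid transport gave 0, 8 and 2 (-0.87, 0.000114, 0.202), the integrated stress response 3, 13 and 2 (-0.86, 1.31e-05, 0.234) and the unfolded protein response 0, 8 and 9 (-0.24, 0.0128, 0.367). MYC targets gave 0, 11 and 10 (-0.35, 0.0286, 0.482), lost with the filter at 5 CPM (0.082). Cytotoxic genes gave 3, 9 and 4 (-0.98, 0.0107, 0.202) and CD8 T cell markers 0, 4 and 0 (-1.93, 0.00154, 0.202). The Th17 program gave 6, 8 and 6 (-0.25, 0.0244, 0.202), lost without shared members (0.941), without pTh17 control library 2 (0.0559) and with the filter at 5 CPM (0.0646). Tfh genes gave 3, 5 and 2 (-0.16, 0.0499, 0.202), lost with the replicate block (0.0692), with the filter at 5 CPM (0.0646) and without Th1 control library 1 (0.0613), 2 (0.0547) or 3 (0.0617), Th1 BTP2 library 2 (0.0581), pTh17 control library 2 (0.0542) or pTh17 BTP2 library 2 (0.0993). NFAT genes gave 7, 11 and 6 (median -0.26, adjusted p = 0.13, but 0.00118 without shared members) and store-operated calcium entry 5, 11 and 6 (-0.40, 0.117). The Th1 program gave 8, 9 and 3 (0.09, 0.72) and pathogenic Th17 genes 9 (10 adjusted over the list alone), 4 and 6 (0.38, 0.21). Called only under some alternatives were fatty acid oxidation (adjusted p = 0.035 with the replicate block, 0.0454 with library size alone and 0.0363 to 0.049 with 1 of 4 libraries left out), oxidative phosphorylation (0.0333 without pTh17 BTP2 library 3 and 0.049 without pTh17 control library 2) and AP-1 genes (0.017 without pTh17 BTP2 library 3 and 0.0355 without pTh17 control library 1). For the Th1 program, calcineurin components, inhibitory receptors, mitochondrially encoded genes and dendritic cell markers the median, mean and test did not share a sign.

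**Figure D3:**
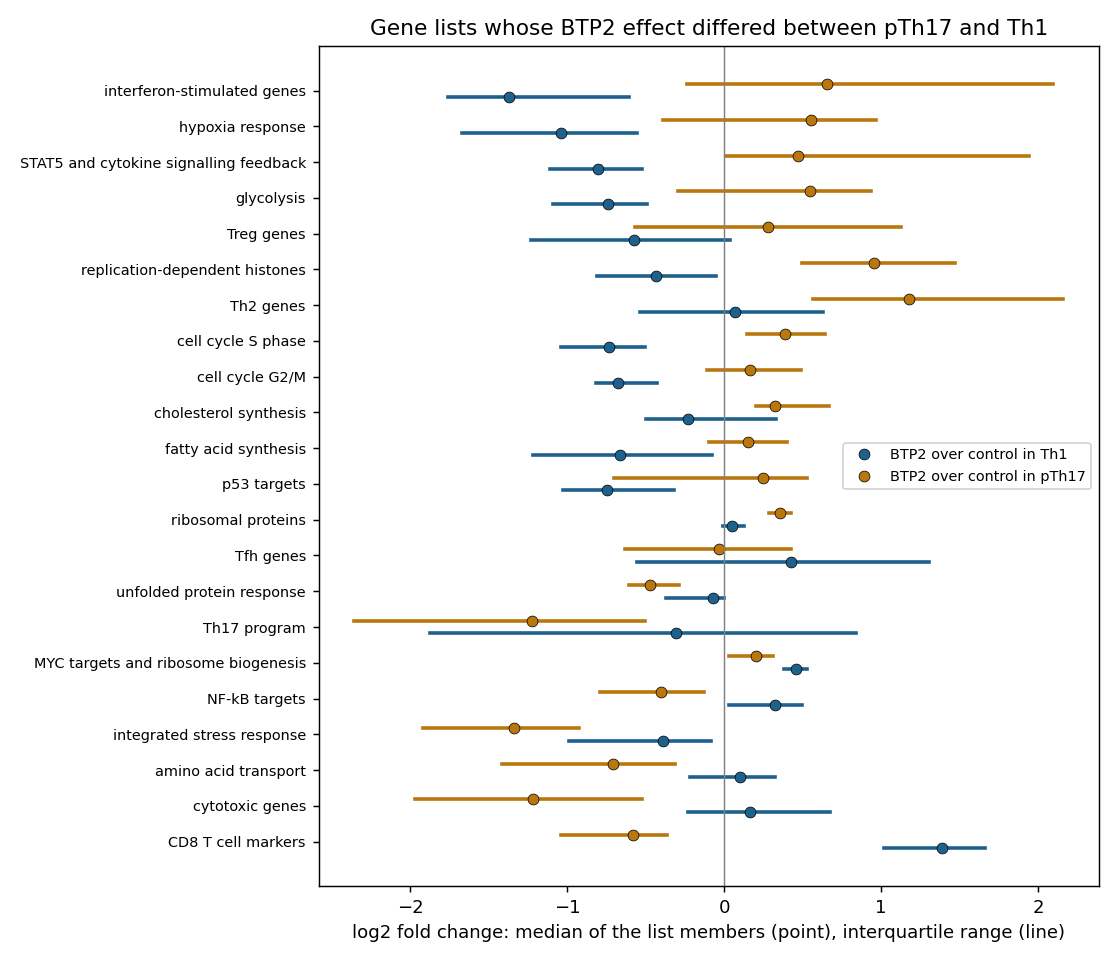
Log2 fold changes of BTP2 over control in Th1 (blue) and pTh17 (orange) for the 22 lists called in the difference, as medians (points) with interquartile ranges (lines) over member genes. Medians for interferon-stimulated genes were -1.37 in Th1 and 0.66 in pTh17, and the Tfh median in pTh17 changes sign under library size alone.

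For the difference 7459 genes passed (3819 higher in pTh17, 3640 lower), 3140 of them by at least 2-fold (1904 and 1236). Library size alone gave 4404 higher and 3069 lower. Of 41 lists, 13 were called up and 9 down, and 0 with an estimated correlation, while 8120 genes passed without adjustment and fry without direction called 40 lists. The 4 groups also differ in CD8 markers (683.8 CPM in Th1 BTP2), B cell markers (145.5 CPM in pTh17 BTP2) and Y-linked RNA (pTh17 controls), so these move with the differences listed.

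The fourth comparison asks how the lineages differed without BTP2. Ifng was 42.6-fold lower in pTh17 (8719 ± 458 against 201.2 ± 13.3 CPM, n = 3, adjusted p = 1.6e-14). Il17a and Il17f were 85.1-fold (2.72 ± 0.79 against 228.5 ± 20.5 CPM) and 143.5-fold higher (adjusted p = 7.78e-13 for Il17f). Tbx21 was 3.65-fold lower. Il2 was 17.4-fold higher in pTh17 (265 ± 38.1 against 4528 ± 262 CPM, adjusted p = 2.57e-10) and Il10 18.9-fold lower (2.72e-11). Csf2 measured 338.4 ± 49.4 and 304.1 ± 11.7 CPM (log2 fold change -0.13, adjusted p = 0.514).

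Ccl20 was 241-fold higher in pTh17, from 0.426 ± 0.162 CPM. Besides Ifng, the largest falls under the naming rule were the serpin gene Serpinb5 (59.2-fold, from 11.4 ± 3.64 CPM) and the Th1 homeobox gene Hlx (24.2-fold, from 25.01 ± 2.98 CPM). Next came Xist (23.4-fold), Il24 (20.6-fold, from 221.8 ± 22.4 CPM) and Gad2 (20.5-fold, from 15.82 ± 1.93 CPM). Y-linked genes were higher in pTh17 controls: Kdm5d at least 717-fold (2020 counts against 0), Ddx3y by a ratio of 3120 (5862 against 2, 95% interval 863 to 25800), Eif2s3y of 1500 (4231 against 3, 513 to 7280) and Uty of 437 (822 against 2, 121 to 3620). Leaving out 1 library moved the log2 fold change of Eif2s3y from 10.40 to 11.23 (Th1 control library 2) and of Uty from 8.54 to 11.13 (Th1 control library 3). Together with Xist, this sex-linked difference accompanies every gene group in this comparison.

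The Th1 program gave 3 higher, 13 lower and 4 not passing in pTh17 (median -1.09, adjusted p = 3.81e-10, and 0.00333 with an estimated correlation). Il12rb2 was 5.42-fold lower from 693.1 ± 76.8 CPM. The Th17 program gave 13, 4 and 3 (1.05, 4.1e-07, and 0.00953 with an estimated correlation). Pathogenic Th17 genes gave 3, 11 and 5 (-0.998, 9.31e-06, and 0.00953 with an estimated correlation, but 0.312 without shared members), where the chemokine gene Ccl3 fell from 4094 ± 405 to 400.4 ± 6.96 CPM. Non-pathogenic Th17 genes gave 1, 6 and 2 (-0.87, 9.35e-05, and 0.0209 with an estimated correlation, but 0.0702 without shared members). Maf was 6.10-fold lower from 225.1 ± 48.1 CPM. The integrated stress response gave 18, 0 and 0 (1.31, 4.99e-22, and 0.0314 with an estimated correlation), with Chac1 19.3-fold and Trib3 11.6-fold higher. Treg genes gave 3, 8 and 3 (-0.50, 0.00867, and adjusted p = 0.34 with an estimated correlation), and without shared members the test changed sign (0.82).

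The remaining called lists lost the call with an estimated correlation, and the brackets give the median, the camera adjusted p and that adjusted p. Amino acid transport gave 9 higher, 0 lower and 1 not passing (0.67, 1.73e-05, 0.152) and the unfolded protein response 10, 0 and 7 (0.23, 0.0103, 0.476). AP-1 genes gave 11 (12 adjusted over the list alone), 5 and 4 (0.62, 0.000271, 0.366), and Egr1, an immediate early transcription factor, was 4.78-fold higher from 161.8 ± 13.1 CPM. NF-kB targets gave 15, 3 and 1 (0.64, 0.00208, 0.34) and store-operated calcium entry 13, 2 and 7 (0.40, 0.00236, 0.34). NK cell markers gave 5, 0 and 1 (1.47, 0.00443, 0.122) and Tfh genes 5, 3 and 2 (0.28, 0.0218, 0.152). Naive and memory genes gave 7, 4 and 5 (0.04, 0.00589, 0.34), with Id3 higher by 25.2-fold from 14.8 ± 1.95 CPM. G2/M genes gave 12, 0 and 8 (0.42, 0.0218, 0.75), a call lost without Th1 control library 3 (0.0732) and with the filter at 5 CPM (0.0664).

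On the lower side in pTh17 controls, glycolysis gave 2, 12 (13 adjusted over the list alone) and 4 (-0.84, 2.75e-05, 0.34), and the pyruvate kinase gene Pkm was 2.58-fold lower from 2594 ± 153 CPM. Ribosomal proteins gave 0, 29 (30 adjusted over the list alone) and 1 (-0.34, 0.000151, 0.476). STAT5 feedback genes gave 2, 8 and 2 (-0.96, 0.000271, 0.377), with Socs3 lower by 10.9-fold from 61.02 ± 4.03 CPM. The labels give IL-2 in the medium after 48 h for Th1 cells and not for pTh17, so this list and Il2 compare cultures that also differ in added IL-2. S phase genes gave 1, 11 and 6 (-0.42, 0.0078, 0.628) and hypoxia genes 4, 11 and 2 (-0.78, 0.0224, 0.565), the latter lost with the filter at 5 CPM (0.0841). NFAT genes gave 10, 9 and 5 (median 0.07, adjusted p = 0.181), with Cd69 higher by 12.0-fold, and without shared members the test changed sign (0.000105). Uncalled lists that passed without shared members were Th2 (0.0498), p53 targets (0.0145) and cytotoxic genes (0.0088), and oxidative phosphorylation passed without pTh17 control library 2 (0.0377). Among uncalled lists the median, mean and test did not share a sign for Th2, NFAT, calcineurin, inhibitory receptors, fatty acid synthesis and chemokines.

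Markers of other cell types also differed between the controls alongside every group above. NK cell markers, called above, summed to 17 ± 0.51 CPM in Th1 and 44.61 ± 1.17 CPM in pTh17. CD8 T cell markers gave 2 higher and 0 lower of 4 (adjusted p = 0.629), with sums of 243.2 ± 28.6 and 282 ± 13 CPM, Cd8a higher by 1.08 and Cd8b1 by 0.93 in log2. Dendritic cell markers gave 6 and 1 of 8 (0.118), with sums of 203.3 ± 14.2 and 137.6 ± 7.86 CPM and H2-Ab1 4.94-fold lower. B cell markers gave 5 and 1 of 10 (0.181), with sums of 34.62 ± 3.42 and 41.12 ± 2.26 CPM, and myeloid markers 3 and 2 of 6 (0.502), with sums of 13.08 ± 1.49 and 16.15 ± 0.865 CPM.

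In the controls 7680 genes passed (3897 higher in pTh17, 3783 lower), 2282 of them by at least 2-fold (1049 and 1233). With library size alone the majority turned, to 3701 higher and 3984 lower. Of 41 lists 11 were called up and 9 down, 5 of them with an estimated correlation. The comparison joins lineage with sex-linked RNA and with markers of other cell types, and each side is 1 pool.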

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

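The tests on sex-linked transcripts, on T cell genes, on the animals in the pools and on B cells in treated libraries were chosen after those results were seen, while the other tests in this section were fixed beforehand. The genes and lists in the next paragraph were picked out because the BTP2 effect differed between pTh17 and Th1.

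The number of genes whose BTP2 effect differed between the lineages was 7459, and 3140 differed by at least 2-fold. In log2, the effect was higher in pTh17 for Hspa1a (8.70), Hspb1 (8.62), Hspa1b (7.78), Cpne6 (7.41), Mcf2l (7.31), Tbx21 (1.67), Il10 (1.56) and Ifng (1.07). It was lower in pTh17 for Ccl20 (-8.90), Wnt3 (-7.05), Car2 (-5.65), Il2 (-4.49), Il17a (-4.43) and Il17f (-3.99). The Y-linked genes Kdm5d (-12.40), Eif2s3y (-10.86) and Ddx3y (-9.07) passed too. Summed Y-linked counts were 4104 to 4606 in pTh17 control libraries and 1 to 10 in each library of the other groups. Those values mark the sex-linked difference of the pTh17 controls and are not read as an effect of BTP2. Without Th1 BTP2 library 2 the values were 11.67 (Hspa1a), 12.76 (Hspb1) and 9.65 (Hspa1b), and without Th1 BTP2 library 3 Kdm5d did not pass (-10.51, edgeR adjusted p = 1.0). Of the 22 lists called for the difference, 0 passed with an estimated correlation. Those for Treg, Th2, histones, ribosomal proteins, MYC targets, the Th17 program and Tfh also lost the call under at least 1 other alternative. Median differences were positive for interferon-stimulated genes (2.29), hypoxia (1.59), STAT5 feedback (1.504), glycolysis (1.44), Treg genes (1.39), histones (1.38), Th2 genes (1.35), S phase (1.08), G2/M (0.83), cholesterol synthesis (0.59), fatty acid synthesis (0.56), p53 targets (0.38) and ribosomal proteins (0.32). They were negative for CD8 T cell markers (-1.93), cytotoxic genes (-0.985), amino acid transport (-0.87), the integrated stress response (-0.86), NF-kB targets (-0.81), MYC targets (-0.35), the Th17 program (-0.25), the unfolded protein response (-0.24) and Tfh genes (-0.16).

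For the count of 7459 genes, regrouping the libraries gives no verdict on chance. A regrouping that mixes pools adds the differences between pools to the spread, so it calls fewer genes whatever their cause. The counts show only that libraries of a group were more alike than libraries of different groups. Chance differences between the pools were not tested and stay open. Treatment labels were regrouped within each cell type, with 100 of 200 possible regroupings drawn, and 1 of them, the real one, called as many. The highest other count was 6673, from the 1 drawn regrouping that keeps both real partitions with a label exchanged, and the highest of the rest was 2440. For each comparison of 3 against 3 libraries, 1 of 10 splits called as many genes as the real one, which is itself that split, with 0 genes in the highest other split. Real values were 6846 in Th1, 7389 in pTh17 and 7680 in the controls, and 10 splits are too few for a share under 0.05.

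The pTh17 controls carry Y-linked transcripts and little Xist. A pool of cells from male animals fits: mean Xist was 4.17% of the mean of the other 9 libraries, and X-linked genes that escape inactivation were lower there, with a median log2 difference of -0.49 (Kdm5c -0.53, Kdm6a -0.45, Eif2s3x -0.77, Ddx3x -0.40). A single male among 3 pooled animals with equal shares can be excluded, since the highest Xist level in those libraries was 5.5% of the others. X- and Y-linked genes were 3.92% of the 1938 genes changed at least 2-fold in pTh17, against 3.18% of the tested genes. So few tested genes lie there that they could not have made up most of that result. Effects of sex on genes of other chromosomes were not tested and stay open. An exchange of samples or labels was not tested and stays open, and the recorded sex of each donor animal would be needed to trace it. Of the 4 groups these libraries had the highest Il17a (228.5 CPM) and Il17f (373.9 CPM). Those levels bear on an exchange with Th1 libraries, but not on an exchange between control and BTP2 within pTh17.

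Lower Il17a, Il17f, Ccl20 and Il2 after BTP2 in pTh17 have 3 explanations to set side by side. A lower share of T cells in the treated libraries does not account for the whole of these falls. The median log2 fold change of 6 T cell genes was 0.29 (range -0.07 to 0.60). The level of these genes per cell was not measured, so a smaller loss of T cells is not excluded. An effect of BTP2 and a difference between the animals of each pool cannot be told apart, because Xist in the pTh17 controls was 5% of its level in the treated libraries, which marks different animals. The 3 libraries per condition are taken as technical replicates of 1 pool, so they do not separate these. Replicate pools of the same sex, treated and untreated, would.

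B cell markers were higher in the treated pTh17 libraries. The explanation stays open: B cells in those libraries would raise 10 markers together, and their median log2 ratio of library 1 to libraries 2 and 3 was 1.01 (interquartile range 0.84), but that test restates the excess in library 1 (213 against 109.2 and 114.4 CPM). The cells were naive CD4 T cells by magnetic enrichment. Whether RNA of B cells makes up other rises cannot be told apart from a response of the T cells. Of the genes that rose at least 2-fold, 10.8% (106 of 981) shared that excess in library 1. Those 106 include the B cell markers that rose at least 2-fold. The share among all tested genes was not computed, so 10.8% cannot be read as large or small. The marker sums of libraries 2 and 3 also lay above the 41.12 CPM of the controls, so the remaining genes are not cleared. Counts of B cells in the cultures would settle it.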

How the results depend on the processing

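Leaving out X- and Y-linked genes, and library size alone for lists, were added after the data were seen. The number of genes called fell most under the test against 1.5-fold, which called 1695 in Th1, 1909 in pTh17, 3169 for the difference and 2360 in the controls, against 6846, 7389, 7459 and 7680. At 2-fold or more, the filter at 5 CPM left 950, 900, 1817 and 1057 genes, against 1818, 1938, 3140 and 2282. At 2-fold, limma-trend on log2(CPM + 1) called 943 in Th1, 960 in pTh17 and 1222 in the controls, and without a filter 931, 948 and 1210. DESeq2 called 6597, 7127, 7202 and 7406 genes, and the replicate block 6772, 7334, 7372 and 7633. Without X- and Y-linked genes 6673, 7154, 7229 and 7461 of 13349 genes passed. Leaving out 1 library gave 5814 (without Th1 BTP2 library 3) to 6921 in Th1, 6405 to 7171 in pTh17, 6867 to 7591 for the difference and 6774 to 6909 in the controls.

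Lists depend on the assumed correlation. Camera with an estimated correlation called 0 lists in Th1, 3 in pTh17, 0 for the difference and 5 in the controls, against 15, 17, 22 and 20 at the preset value. Directional fry called 28 lists in Th1 and 30 in pTh17, and fry without direction 40, 40, 40 and 39. Without members shared between lists, the sign of the test changed for Treg genes in Th1 (adjusted p = 0.747) and in the controls (0.82), and for NFAT genes in the controls (0.000105). The replicate block added B cell markers in Th1 (0.0239) and fatty acid oxidation in the difference (0.035), and removed Tfh genes from the difference (0.0692). The log2 fold change of mt-Cytb in pTh17 was -0.18 without pTh17 BTP2 library 2 and 0.20 without library 3 (adjusted p = 0.0422). Of the values for named genes, 10103 were the same under the alternatives, 165 weaker, 18 stronger and 1 reversed. Of those for lists, 2194 were the same, 99 weaker, 74 stronger and 3 reversed.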

Other observations

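The comparison of lineages within the BTP2-treated libraries was chosen after the results were seen. After BTP2, Ifng was still 20.3-fold lower in pTh17 than in Th1 (log2 fold change -4.34, SE 0.11, edgeR adjusted p = 4.16e-13). Il17f was 9.04-fold and Il17a 3.96-fold higher, where the controls gave 143.5-fold and 85.1-fold. Ccl20, higher in pTh17 controls, was 1.97-fold lower in treated pTh17 than in treated Th1 (adjusted p = 0.00223). Tbx21 (log2 fold change -0.20, SE 0.0959, adjusted p = 0.0923) and Il2 (-0.37, SE 0.178, adjusted p = 0.102) did not pass, although each differed between the controls. The epidermal growth factor family gene Areg was 8.79-fold higher, and the chemokine genes Ccl3 and Ccl4 were 7.55-fold and 9.66-fold lower. Ddit3 was 1.57-fold and Trib3 1.65-fold higher, and Chac1 1.61-fold lower.

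In this comparison 6726 genes passed (3495 higher in pTh17, 3231 lower), 1861 of them by at least 2-fold (1368 and 493). Of the 2282 genes that differed at least 2-fold between the controls, 430 did so in the same direction after BTP2 and 358 in the opposite one. In the treated groups Y-linked genes were near absent, with 1 to 10 counts per library. Xist was 1.48-fold lower in treated pTh17 (edgeR adjusted p = 0.0443), and Ddx3y, on few counts, 4.94-fold higher (0.0249). These groups also differ in CD8 markers (683.8 and 206.2 CPM, Th1 first) and B cell markers (33.95 and 145.5 CPM). Cd8a was 4.06-fold lower and Ighm 3.63-fold higher in treated pTh17.

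Treated libraries spread more within their group than controls: the median SD of log2 CPM was 0.102 in Th1 controls, 0.137 in Th1 BTP2, 0.105 in pTh17 controls and 0.16 in pTh17 BTP2. Mitochondrially encoded transcripts summed to 14390 ± 518, 13600 ± 1060, 12020 ± 1080 and 11870 ± 3170 CPM in the same order. In pTh17 BTP2 libraries 1, 2 and 3 the sums were 12550, 14640 and 8413 CPM. Library 3 of that group also had the lowest total, 15148632 counts. The first 3 principal components held 37.6%, 28.1% and 18.5% of the variance. On component 1 the pTh17 controls lay at 60.58 to 62.21 and all other libraries at -31.52 to -3.015. The largest axis thus made the same split as Y-linked RNA. The median gene of the difference lay at 0.102 in log2 with library size alone and at 0.00765 with TMM.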
